A study of Mus musculus with 4 samples.

How the data were processed

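Deposited count matrices of 4 single-cell RNA-seq libraries were analysed, 1 for each combination of treatment (vehicle or imeglimin) and glucose (3.9 or 11.1 mM). Per the labels, islets of wild-type C57BL6J male mice aged 8 weeks were cultured for 24 h with 1 mM imeglimin or DMSO vehicle, dispersed with Accutase, and made into 10x 3' libraries. According to the submitters' processing notes, reads were aligned to mm10 and counted with Cell Ranger 6.0.2. The deposited values were whole-number UMI counts per gene and barcode, and were used as raw counts. All 4 matrices were used. Of 32285 gene identifiers, 32158 (99.6%) were found in GENCODE vM21, the annotation release on GRCm38 that was used for gene positions.

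The comparisons, the cell limits, the marker genes of each cell class, the 26 fixed gene lists, the rule for naming genes and most alternatives were set before the data were examined. Chosen after the data were examined were the details of the cluster scoring rule, the list of snoRNA host genes, the rules for naming genes in pp-, endothelial- and macrophage-like cells, the wording of the self-test criterion, and the added alternatives named as such with the results.

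Barcodes with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs were kept. Doublets were scored in each library with scrublet at an expected rate of 0.8% per 1000 barcodes. The caller did not work: it called 2, 1, 4 and 0 doublets in the vehicle 3.9 mM, imeglimin 3.9 mM, vehicle 11.1 mM and imeglimin 11.1 mM libraries. In the added alternative the highest scores, up to the expected rates of 6.02%, 7.17%, 6.00% and 6.77%, were left out instead.

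Counts were log-normalised for clustering. The 2000 most variable genes were chosen by rank within each library, 30 principal components and 15 neighbours were used, and Leiden clusters were drawn at resolution 1 on the 4 libraries together, without integration. A cluster was named for the class with the highest marker score when at least 3 of that class's markers were detected. Mixed clusters, those with more markers of another class among their top genes, and those with far fewer UMIs than their library stayed unnamed. The 2nd-highest score did not decide this alone. A cluster at 1 for acinar and 0.404 for beta stayed unnamed as mixed. Another at 0.474 for macrophage and 0.452 for dendritic was named. Marker sets covered beta, alpha, delta, pp, acinar, duct, endothelial, stromal, Schwann, macrophage, dendritic, neutrophil, T and NK, B and erythroid cells. Class names carry the ending "-like" because they rest on RNA alone.

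UMIs were summed over the cells of a class in each library, scaled with the trimmed mean of M-values (TMM, edgeR) over the 4 sums, and given as CPM, that is, counts brought to a common library total. A gene was compared when it reached 20 CPM in beta-like cells, or 50 CPM in alpha- or delta-like cells, in either library. With 1 library per condition no test was made between conditions, cells were not treated as replicates, and there is no replicate check on any difference. Intervals are 95% exact Poisson intervals for sums and exact Clopper-Pearson intervals for shares of cells. They cover counting error only, not variation between mice, cultures or library preparations. Intervals for sums also leave out variation between cells, so a few cells with many UMIs of a gene can set a ratio. Genes at least 1.5-fold apart were counted as a measure of size, not as changed genes. A sum of 0 was replaced by 3 UMIs.

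Genes were named by a fixed rule. In beta-like cells these were the 12 highest and 12 lowest ratios of at least 1.5-fold with the same direction under plain CPM and under the mean of per-cell CPM. In alpha- and delta-like cells they were the 5 highest and 5 lowest. Wherever the mean of per-cell CPM was used, its ratios were centred on their median over genes with at least 20 CPM in either library. Unnamed gene models were left out, as were genes over 10 times higher in another class of at least 50 cells in the same library, whose values free RNA in the suspension can set. To these were added 18 genes named in advance and up to 4 members of each list that stood apart. Genes from these additions that were over 10 times higher in another class are said to be so. Some genes that met the rule are not reported here.

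For each fixed list the median log2 ratio of members with at least 5 CPM was placed among 10000 random lists of the same size, matched on mean expression in 50 bins. A list stood apart below percentile 2.5 or above percentile 97.5. Percentiles describe these libraries and are not tests. TMM, plain CPM and CPM without hormone and mitochondrial genes differ only in the library total, which moves all genes of a comparison by the same amount, so the choice between them leaves list percentiles in place but can turn the sign of a median. The lists cover beta-cell identity, genes disallowed in beta cells, secretory granules and exocytosis, the integrated stress response and the unfolded protein response. Those of metabolism cover nuclear-encoded oxidative phosphorylation, the mitochondrial genome, the TCA cycle, mitochondrial biogenesis, mitochondrial chaperones, NAD metabolism, purine synthesis, glycolysis, ChREBP targets and lipogenesis, cholesterol synthesis and fatty acid oxidation. The others cover proliferation, G1 cyclins and CDK inhibitors, apoptosis and p53, NRF2 targets, hypoxia, immediate early genes, NF-kappaB, and interferon and antigen presentation. There are also lists of autophagy and lysosome, and of heat shock and dissociation, called heat shock below.

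A cell was counted as dividing when, after thinning to 3000 UMIs, it held UMIs of at least 3 of 15 division genes. Seeds were fixed (7). Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.

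The ratios and list percentiles were tried on simulated counts with 200 genes made 2-fold or 3-fold different. Simulated on the comparison of imeglimin and vehicle at 11.1 mM in beta-like cells, 97% of 2-fold and 99% of 3-fold genes were recovered past 1.5-fold, out of 5030 genes run. On the comparison at 3.9 mM in alpha-like cells, the poorest of the 12 class and comparison pairs, it was 92% and 91% out of 2708 genes. Of the changed genes that passed the expression minimum, between 98.98% and 100% were recovered over the 12 pairs. The criterion was first set on all changed genes, which failed in alpha-like cells because changed genes fell under the minimum, and was then set on compared genes. Of 500 random lists in each pair, between 3.2% and 6.8% stood apart where 5% is the nominal share. Each pair was drawn from 1 profile with counting error only, with as many genes raised as lowered. The simulation therefore does not test the scaling where many genes differ, nor lists of genes that vary together.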

Results

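Islet cells cultured for 24 h in 4 conditions gave 7164 kept cells for vehicle at 3.9 mM glucose, 8754 for imeglimin at 3.9 mM, 7440 for vehicle at 11.1 mM and 8427 for imeglimin at 11.1 mM. Insulin-producing beta-like cells were the largest class everywhere, with glucagon-producing alpha-like cells next. Beta-like cells made up 65.3% of cells (95% counting interval 64.2 to 66.4) with vehicle at 3.9 mM, 51.1% (50.1 to 52.2) with imeglimin at 3.9 mM, 65.3% (64.2 to 66.4) with vehicle at 11.1 mM and 64.2% (63.2 to 65.2) with imeglimin at 11.1 mM. In the same order alpha-like cells made up 9.16%, 12.8%, 8.58% and 10.1%, somatostatin-producing delta-like cells 3.48%, 4.88%, 4.31% and 3.41%, and pp-like cells, which express pancreatic polypeptide, 1.24%, 2.17%, 1.14% and 1.42%. Endothelial-like cells made up 1.41%, 2.89%, 2.14% and 3.8%, but 1.25%, 1.59%, 1.53% and 1.61% of cells with at least 3000 UMIs. At cluster resolution 0.5 they made up 2.39%, 4.67%, 2.96% and 5.01%. Macrophage-like cells made up 1.47%, 0.971%, 1.69% and 1.78%, but with imeglimin at 3.9 mM 1.51% at cluster resolution 0.5 and 1.61% from clusters of that library alone. From clusters of its library alone, pp-like cells with imeglimin at 11.1 mM were 0%. Stromal-like cells made up between 0.586% and 0.780%, but with imeglimin at 3.9 mM 1.68% from clusters of that library alone. Only 4, 13, 7 and 7 duct-like cells were found.

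Cells left without a class made up 17.3%, 24.4%, 15.9% and 14.5%. The lower beta-like share with imeglimin at 3.9 mM went only in part with an unnamed cluster of few UMIs, which held 9.73% of that library's cells against 3.5%, 0.255% and 0.249% of the others. Among cells with at least 3000 UMIs the beta-like share at 3.9 mM was still 58.0% with imeglimin and 68.6% with vehicle. Most other unnamed clusters mixed markers of more than 1 endocrine class. Of barcodes that passed the UMI and gene minimum, 4.83%, 2.29%, 0.733% and 0.414% were over the mitochondrial limit. Of all barcodes, 13.4%, 8.42%, 5.21% and 3.74% were over it. Shares describe the suspension after dispersal, not the islet.

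**Figure D1:**
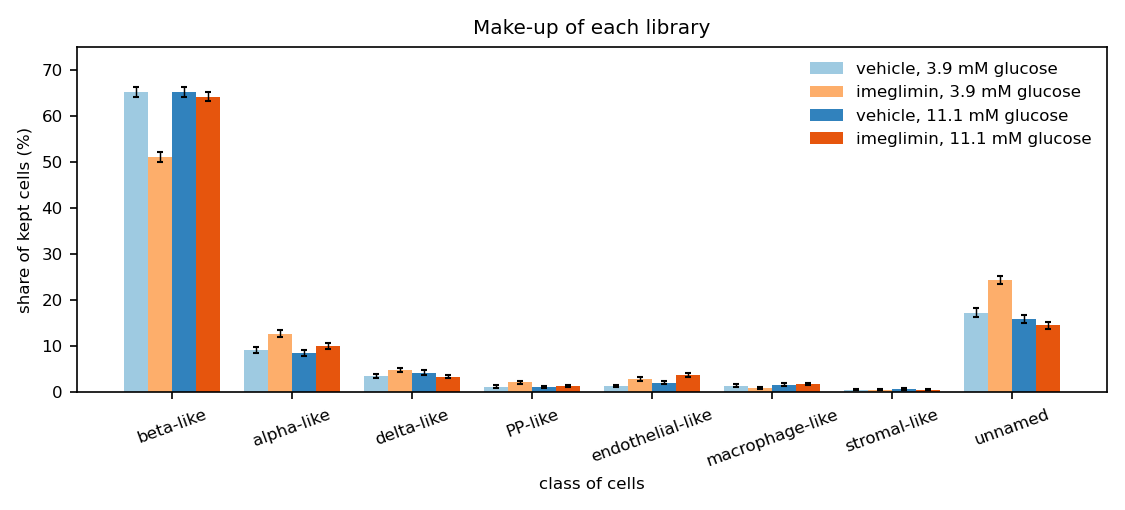
Share of kept cells in each class for the 4 libraries, with 95% counting intervals.

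Imeglimin at 11.1 mM glucose: beta-like cells held more transcripts of the genes Mt1 and Mt2 and of the integrated stress response, and fewer transcripts of genes of mature beta cells, than with vehicle. The highest ratios were those of Mt1 and Mt2, which encode metallothioneins, and of Nupr1, a stress-induced transcription regulator. Vgf, a precursor of granule peptides, Ddit3, the stress transcription factor CHOP, and Trib3, a pseudokinase downstream of ATF4, came next. Among the lowest were the glucose transporter gene Slc2a2, the cation channel gene Trpm5, and Mlxipl, which encodes the glucose-sensing factor ChREBP. Nuclear genes of oxidative phosphorylation were higher as a group.

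In beta-like cells Mt1 was at 9682 CPM with imeglimin and 2480 with vehicle at 11.1 mM (log2 ratio 1.97, counting interval 1.96 to 1.97), Mt2 at 2038 and 551 (1.89) and Nupr1 at 1155 and 321 (1.85, 1.83 to 1.87). Vgf was at 147 and 42.0 (1.80, 1.74 to 1.86), Ddit3 at 396 and 130 (1.61, 1.57 to 1.64) and Trib3 at 79.8 and 26.7 (1.58, 1.5 to 1.66). Further among the 12 highest were Tenm4, a teneurin of cell contacts (1.56), and Odc1, the first enzyme of polyamine synthesis (1.52). The rest were the glutathione transferase gene Gsto1 (1.46), Ccdc107, a membrane protein gene (1.45), the vitamin B12 receptor gene Cd320 (1.44) and the transcription factor gene Etv5 (1.44). Lowest were the heat shock genes Hspa1b, at 12.4 and 148 CPM (-3.58), and Hspa1a, at 13.9 and 137 (-3.31). These are near-identical neighbours, so the split between them is uncertain. In an alternative added after the data were examined, without 2 clusters led by these genes, Hspa1b was at -0.00497 and Hspa1a at -0.09. Trpm5 was at 6.18 and 61.5 CPM (-3.31, -3.46 to -3.17), the crystallin gene Crybb3 at 18.7 and 144 (-2.95), Mlxipl at 16.9 and 81.1 (-2.27, -2.36 to -2.17). Ddc, an aromatic amino acid decarboxylase gene, was at 54.0 and 192 (-1.83), Fkbp1b, which binds calcium release channels, at 38.7 and 136 (-1.81) and Slc2a2 at 76.2 and 254 (-1.74, -1.78 to -1.69). The others were T2 (-2.50), the aldo-keto reductase gene Akr1c19 (-2.07), the membrane protein gene Fam151a (-2.01) and Banp, a nuclear matrix protein gene (-1.66). Over the 70 genes named in this comparison the median width of the counting interval was 0.12, and the widest was 0.60 for Mki67.

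Of the genes named in advance, Ins1 was at 85004 CPM with imeglimin and 119410 with vehicle (-0.49), whereas Ins2 (238350 and 250940, -0.07) and the amylin gene Iapp (104260 and 101530, 0.04) were nearly level in beta-like cells at 11.1 mM. Mafa, a transcription factor of mature beta cells, was lower (310 and 526, -0.76). Atf4, the central factor of the integrated stress response, was higher (322 and 185, 0.80), as were Ppp1r15a, which restarts translation (0.76), and Hspa5, the endoplasmic reticulum chaperone BiP (1834 and 1131, 0.70). Nampt, of NAD salvage, was at 0.26, the purine enzyme gene Adsl at -0.01 and the proliferation gene Mki67, at 2.02 and 4.19 CPM, at -1.06 (-1.36 to -0.76). Txnip, which inhibits thioredoxin (20.2 and 48.3, -1.26), Cdkn1a, the cell cycle inhibitor p21 (0.57), Gdf15, a stress hormone (-0.03), and Gcg (-0.31) were over 10 times higher in another class in at least 1 library, so their ratios in beta-like cells are open to free RNA.

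Of the 26 fixed lists, 4 stood apart upwards and 8 downwards in beta-like cells at 11.1 mM. The integrated stress response list had a median log2 ratio of 0.40 (percentile 100; 11 of 35 members at least 1.5-fold higher, 0 lower). The unfolded protein response list was at 0.38 (percentile 99.9; 7 of 30 higher), led by Derl1, of endoplasmic reticulum protein export (0.81), Creld2 (0.78) and Sdf2l1 (0.69), both folding factors. Nuclear genes of oxidative phosphorylation had a median of 0.36 (percentile 100; 9 of 74 higher), led by Uqcrq of complex III (624 and 309 CPM, 1.01), Ndufa3 (0.97) and Ndufa5 (0.95) of complex I and Atp5k of the ATP synthase (0.85). Mitochondrial chaperones and proteases were at 0.36 (percentile 99.5), led by the protease gene Lonp1 (0.92) and the chaperone gene Hspa9 (500 and 281 CPM, 0.83), with Dnaja3 at 0.59 and Hspe1 at 0.50. The identity list was at -0.49 (percentile 0; 13 of 27 lower, 0 higher), with the incretin receptor gene Glp1r at 171 and 459 CPM (-1.42) beside Trpm5, Slc2a2 and Mafa.

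Lower lists in beta-like cells at 11.1 mM further included ChREBP targets and lipogenesis (median -0.25, percentile 0.07), with the citrate lyase gene Acly at 398 and 619 CPM (-0.64) and Srebf1, a regulator of lipid synthesis (-0.48). Glycolysis was at -0.10 (percentile 0.2), with Aldoc, an aldolase gene (-0.80), and Gpd2, of the glycerol phosphate shuttle (-0.72). The disallowed gene list had 4 measured members (-0.59, percentile 1.3). Secretory granule genes were at -0.06 (percentile 0.275) while their mean was 0.01, with Sytl4 (-1.08), Rph3al (-0.65) and Cadps (-0.65), all of granule docking or priming, and the granule protein gene Chga (-0.67) lower. Heat shock genes were at -0.13 (percentile 1.15), with Hspb1, over 10 times higher in another class, at -3.16 and Dnaja1 at -0.28. Without the 2 clusters led by Hspa1a and Hspa1b, the list was at 0.30 (percentile 90.7) and Hspb1 at 0.32. Interferon and antigen presentation genes were at -0.11 (percentile 1.95), with the transcription factor gene Irf1 at -0.75 and Psmb8 (-0.72), B2m (-0.12) and H2-D1 (-0.11) open to free RNA. A cluster led by the interferon genes Rsad2 and Ifit3 held 2.46% of beta-like cells with imeglimin and 0.679% with vehicle. The lower interferon median therefore did not go with a smaller share of such cells. Mitochondrially encoded genes had a median of 0.01 that lay low among matched lists (percentile 2.32) and fell to -0.04 under plain CPM. Inside that list mt-Nd3 was at 0.53, mt-Atp8 at 0.44 and mt-Nd1 at 0.25.

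Beta-like cells had a median of 12849 UMIs with imeglimin and 13061 with vehicle at 11.1 mM, and the nuclear RNA Malat1 made up 2.49% and 1.31% of all UMIs in these libraries. In beta-like cells with at least 10000 UMIs and at most 5% mitochondrial UMIs, an alternative added after the data were examined, the integrated stress response was at 0.35, the unfolded protein response at 0.34, nuclear oxidative phosphorylation at 0.31 and identity at -0.50. Heat shock was at -0.36, glycolysis at -0.21 and interferon at -0.21 there. All of these stood apart in the same direction as in all cells. The mitochondrially encoded list no longer stood apart (percentile 3.5), and NF-kappaB, not apart in either, turned from 0.11 to -0.10.

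Not apart in any beta-like comparison were NAD metabolism (0.11 with imeglimin at 11.1 mM, percentile 60.0), the TCA cycle (0.21, percentile 93.9), mitochondrial biogenesis (0.21, percentile 92.4), purine synthesis (-0.01, percentile 12.4), G1 cyclins and CDK inhibitors (-0.03, percentile 14.3), NRF2 targets (0.12, percentile 44.3) and autophagy and lysosome (0.10, percentile 39.3). Fatty acid oxidation (0.05), cholesterol synthesis (-0.02), proliferation (-0.16), apoptosis and p53 (0.14), hypoxia (0.18), immediate early genes (0.11) and NF-kappaB (0.11) did not stand apart with imeglimin at 11.1 mM either.

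By size, 318 of 5626 genes were at least 1.5-fold higher and 243 lower with imeglimin at 11.1 mM in beta-like cells. The balance rested on the scaling and on the choice and depth of cells. Thinning to 3000 UMIs gave 290 higher and 317 lower, and deep cells 256 and 278. Plain CPM gave 246 higher and 283 lower, CPM without hormone and mitochondrial genes 127 and 448, which moved the median ratio by -0.19, and the mean of per-cell CPM 174 and 349. Vehicle cells at 11.1 mM lay mostly in 1 cluster (72.1% of beta-like cells) and imeglimin cells mostly in 2 others (52.9% and 20.2%).

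**Figure D2:**
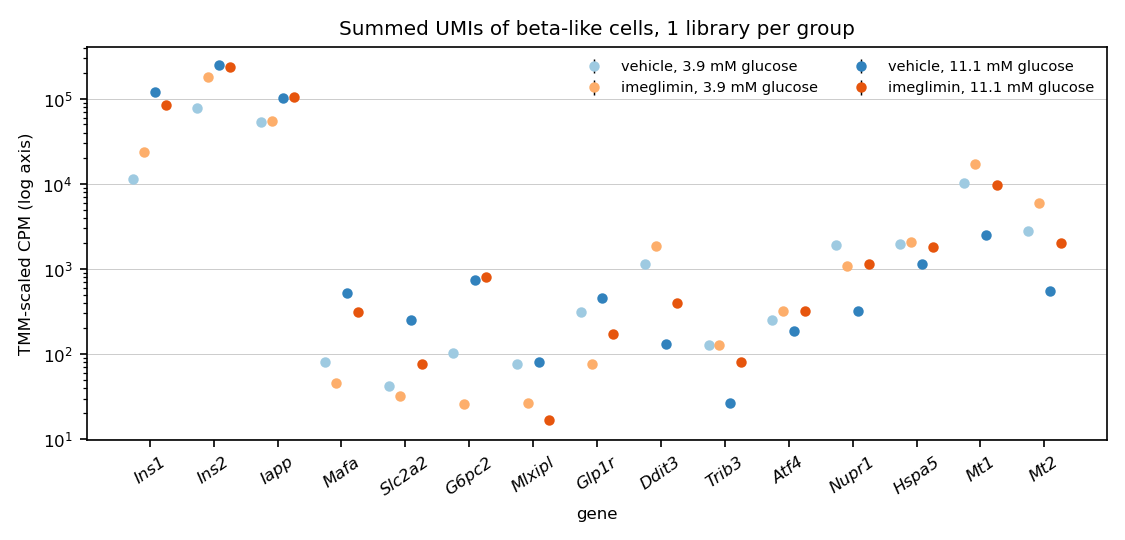
CPM of 15 genes in beta-like cells of the 4 libraries, on a log axis, with 95% counting intervals.

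Imeglimin at 3.9 mM glucose: beta-like cells again held fewer transcripts of mature beta-cell genes, with Crybb3, Glp1r and the glucose-6-phosphatase gene G6pc2 among the lowest. Both insulin genes were higher, in contrast to 11.1 mM. Genes of heat shock, of NF-kappaB signalling and of the p53 response were higher as groups, and genes of glycolysis and lipogenesis lower. The heat shock list, which also covers dissociation, stood apart upwards in alpha- and delta-like cells too. Dispersal stress as its source was not tested at 3.9 mM. Derl3, which exports misfolded proteins from the endoplasmic reticulum, had the highest ratio.

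Derl3 was at 46.9 CPM with imeglimin and 8.01 with vehicle at 3.9 mM in beta-like cells (2.55, 2.42 to 2.68), Rgs16, which damps G protein signals, at 20.3 and 3.91 (2.38) and Tent5a, a poly(A) polymerase gene, at 139 and 28.1 (2.30). Oga, which removes O-GlcNAc, was at 104 and 23.5 (2.14) and the splicing gene Snrnp48 at 198 and 56.4 (1.81). Others among the highest were the MAP kinase phosphatase genes Dusp4 (2.11) and Dusp16 (1.75), the fatty acid elongase gene Elovl7 (1.88) and the arrestin gene Arrdc4 (1.86). The cyclin gene Ccng2 (1.83), Spry2, a brake on growth factor signals (1.81), and Aldh5a1, of GABA breakdown (1.73), completed them. Crybb3 was at 5.10 and 59.4 CPM (-3.54), Glp1r at 75.9 and 314 (-2.05, -2.1 to -2.0) and G6pc2 at 26.1 and 102 (-1.97, -2.05 to -1.89). Also lowest were the adhesion genes Nrcam (-2.50) and Hepacam2 (-2.0), Fam151a (-2.44), T2 (-2.40), and Haghl, a hydrolase-like gene (-2.23). They further included Dtnbos, a non-coding RNA (-2.18), Rasgef1b, a Ras exchange factor gene (-2.03), the iron-siderophore binder Lcn2 (-1.90) and Pbxip1, which binds PBX factors (-1.89). Among the 80 named genes the median width of the counting interval was 0.17, the widest 0.76 for Mki67.

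Ins2 was at 180030 CPM with imeglimin and 77112 with vehicle at 3.9 mM (1.22), and Ins1 at 24022 and 11550 (1.06), with Iapp level (0.04). Mafa was lower (45.8 and 81.2, -0.83), as were Adsl (-0.46) and Slc2a2 (31.7 and 42.6, -0.43). Ddit3 was higher (1875 and 1158, 0.70), with Ppp1r15a at 0.62, Atf4 at 0.35, Nampt at 0.16, Hspa5 at 0.09 and Trib3 level (127 and 126, 0.01). Mki67 was at 2.49 and 1.38 CPM (0.85, 0.47 to 1.23). Plain CPM moved every ratio of this comparison by -0.30, so the signs of Nampt, Hspa5, Trib3 and Iapp rest on the scaling. Higher in another class, and so open to free RNA, were Txnip (28.0 and 9.73, 1.52), Cdkn1a (339 and 167, 1.02), Gcg (0.93) and Gdf15 (0.80).

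In beta-like cells at 3.9 mM, 5 lists stood apart upwards. The NF-kappaB list was at 0.81 (percentile 99.98; 5 of 8 higher), with its inhibitor gene Nfkbia at 369 and 83.7 CPM (2.14, higher in another class), Nfkbiz, an inducible regulator, at 1.16 and Relb, higher in another class, at 1.02. Immediate early genes were at 0.65 (percentile 99.99), with the insulin receptor substrate gene Irs2 at 1.18 and Jun (2.82), Atf3 (2.10) and Junb (1.16) higher in other classes. Heat shock genes were at 0.64 (percentile 99.98; 6 of 11 higher), with the chaperone genes Hspa8 at 4238 and 1904 CPM (1.15), Hsp90aa1 at 3321 and 1331 (1.32), Dnajb1 at 167 and 53.2 (1.65) and Hsph1 at 0.92. The apoptosis and p53 list was at 0.58 (percentile 100; 8 of 17 higher, 0 lower). It held the cell death gene Bbc3 (1.21), Gadd45a (1.2) and Gadd45b (1.43, higher in another class), both of growth arrest, and Trp53inp1, a p53 cofactor (0.94). Interferon genes were at 0.45 (percentile 99.87), with Ifit3 (1.57), Cxcl10 (1.40) and Bst2 (0.98) higher in other classes.

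Downwards, the identity list was at -0.54 (percentile 0; 11 of 27 lower, 3 higher) in beta-like cells at 3.9 mM, with Mlxipl at -1.50 and Trpm5 at -1.24. Glycolysis was at -0.65 (percentile 0; 12 of 19 lower, 0 higher), with Aldoa at 276 and 562 CPM (-1.03), Eno1 (-1.01), Tpi1 (-0.93) and Pgk1 (-0.93), which encode enzymes of the pathway. ChREBP targets and lipogenesis were at -0.66 (percentile 0.01; 8 of 16 lower), with Acly at 141 and 356 CPM (-1.33) and the desaturase gene Scd2 (-1.11). Hypoxia genes were at -0.36 (percentile 0.23), with the oxidoreductase gene Ero1l (-1.05), the mitophagy gene Bnip3 (-0.82) and the kinase gene Pdk1 (-0.71). Fatty acid oxidation was at -0.35 (percentile 1.52), with the thiolase gene Acaa2 at -1.17. Secretory granule genes were at -0.20 (percentile 0.04), with Cadps (-0.91), Sytl4 (-0.82) and Ptprn, a granule membrane protein (-0.82). The integrated stress response list did not stand apart (0.23, percentile 91.8; 9 of 33 higher, 3 lower), and its median was below 0 under plain CPM. Nuclear oxidative phosphorylation genes were at 0.11 (percentile 38.1), the unfolded protein response at -0.01 (percentile 2.77) and proliferation at 0.32 (percentile 97.0).

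The libraries also differed in depth and in nuclear RNA: beta-like cells had a median of 10059 UMIs with imeglimin and 12111 with vehicle at 3.9 mM, and Malat1 made up 3.13% and 1.76% of all UMIs. In beta-like cells with at least 10000 UMIs and at most 5% mitochondrial UMIs, an alternative added after the data were examined, heat shock genes were at 0.62, NF-kappaB genes at 0.71 and p53 genes at 0.54, each above percentile 99.9. Fatty acid oxidation no longer stood apart in these cells (-0.34, percentile 2.53), while proliferation did (0.34, percentile 97.7).

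At 3.9 mM, 742 of 6002 genes were at least 1.5-fold higher and 625 lower in beta-like cells with imeglimin. Plain CPM gave 223 and 1333, with a median shift of -0.30, CPM without hormone and mitochondrial genes 389 and 904, and the mean of per-cell CPM 557 and 866. One cluster held 88.8% of the beta-like cells with vehicle, and 2 others held 58.4% and 24% with imeglimin. Small clusters led by Nfkbia and Birc3 (7.31%) and by the interferon genes Rsad2 and Ifit3 (6.84%) held further beta-like cells of the imeglimin 3.9 mM library. With vehicle at 3.9 mM these small clusters held 1.2% and 1.92%.

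The imeglimin ratios at the 2 glucose levels, which share no library, had a Pearson correlation of 0.38 over 6349 genes in beta-like cells (Spearman 0.33). At least 1.5-fold higher at both levels were 98 genes where independent sets would give 44.3, lower at both were 146 against 29.8, and 34 were opposite. Crybb3, Fam151a, T2 and Glp1r were among the genes lower at both. In alpha-like cells the correlation was 0.86 over 3407 genes, with Mt1, Vgf and Mthfd2 higher at both levels and Edn3, Pdk4 and Mapk15 lower. The scatter of the ratios also labels Ddit3 in alpha-like cells, a gene chosen after its values were seen.

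**Figure D3:**
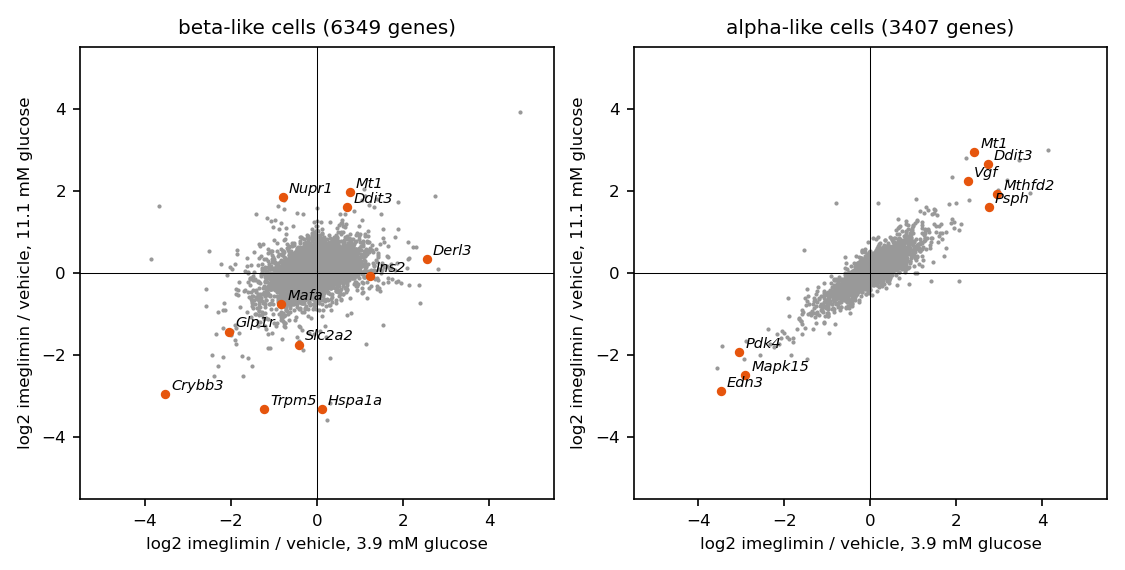
Log2 ratio of imeglimin to vehicle at 3.9 mM (horizontal) and at 11.1 mM glucose (vertical) for each gene, in beta-like cells (left) and alpha-like cells (right).

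High against low glucose with vehicle: beta-like cells at 11.1 mM held more insulin transcripts, more transcripts of glycolysis genes, and fewer transcripts of the integrated stress response than at 3.9 mM. Ins1, Mafa, G6pc2 and Slc2a2 were among the highest ratios. Ddit3 had the lowest, and 6 of the 12 lowest named genes, such as Snhg1 and Snhg6, host small nucleolar RNAs. Lists of cholesterol synthesis, secretory granule and hypoxia genes were higher.

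Pdyn, the prodynorphin gene, was at 142 CPM at 11.1 mM and 5.38 at 3.9 mM in vehicle beta-like cells (4.72, 4.58 to 4.87), the chloride channel gene Ttyh1 at 41.0 and 2.21 (4.21) and Ins1 at 119410 and 11550 (3.37). G6pc2 was at 748 and 102 (2.87), Mafa at 526 and 81.2 (2.69) and Slc2a2 at 254 and 42.6 (2.58). Others among the highest were the cyclic nucleotide phosphodiesterase gene Pde10a (3.29), Mrln, a regulator of the calcium pump (3.1), and Cbs, of hydrogen sulfide and cysteine synthesis (2.91). Tent5a (2.77) and the prolactin receptor gene Prlr (2.62) came next. Lowest were Ddit3 at 130 and 1158 CPM (-3.15, -3.19 to -3.12), the metalloreductase gene Steap1 (-2.79), the ectonucleotidase gene Entpd2 (-2.78) and Snhg6 (-2.78). The others were Epb41l4aos (-2.76), Snhg1 at 59.1 and 377 (-2.67), Snhg12 (-2.58), Nupr1 at 321 and 1910 (-2.57), Zfas1 (-2.53), Hnf1aos1 (-2.45), Snhg5 (-2.45) and Mt2 at 551 and 2781 (-2.33). Of these Snhg6, Snhg1, Snhg12, Zfas1, Snhg5 and Epb41l4aos host small nucleolar RNAs, and Hnf1aos1 is an antisense RNA. Counting intervals of the 83 named genes had a median width of 0.13, the widest 0.74 for Fos.

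Ins2 was at 250940 and 77112 CPM (1.70) and Iapp at 0.94 at high against low glucose in vehicle beta-like cells. Trib3 (-2.24), Ppp1r15a (-1.32), Hspa5 (-0.78), Atf4 (-0.43), Nampt (-0.38) and Adsl (-0.29) were lower, and Mki67 was at 1.60. Open to free RNA were Txnip (2.31), Gcg (1.08), Cdkn1a (-0.69) and Gdf15 (-1.83).

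With vehicle 11 lists stood apart upwards at 11.1 mM in beta-like cells. Glycolysis was at 1.23 (percentile 100; 14 of 19 higher), with Aldoc (1.86), the phosphofructokinase gene Pfkp (1.59) and Pgk1 at 463 and 158 CPM (1.55). Immediate early and CREB genes were at 1.37 (percentile 100), with the prohormone convertase gene Pcsk1 at 345 and 121 CPM (1.51) and Fos (5.38) and Egr1 (4.82) higher in other classes. Hypoxia genes were at 0.96 (percentile 100; 9 of 15 higher), with Ldha, higher in another class, at 3.69. Identity genes were at 0.94 (percentile 100; 17 of 27 higher, 0 lower) and ChREBP targets and lipogenesis at 0.72 (percentile 100), with Scd2 (1.70) and the fatty acid synthase gene Fasn (1.22). Mitochondrially encoded genes were at 0.72 (percentile 100; 7 of 13 higher), with mt-Nd4 (1.08) and mt-Cytb (1.06). Cholesterol synthesis was at 0.70 (percentile 100; 14 of 21 higher), with the sterol pathway genes Idi1 (1.43), Insig1 (1.24) and Hmgcs1 (1.02). Secretory granules were at 0.58 (percentile 100; 11 of 22 higher), with Pam (1.29), Ptprn (1.23), Vgf (1.2) and Chgb (1.09). The disallowed list was at 0.51 (percentile 98.1, 4 measured members). The unfolded protein response list was at 0.10 (percentile 98.6), with Edem2 (1.41) and Sec24d (1.14), of protein quality control and transport. The interferon list was at 0.22 (percentile 98.8), with a mean of -0.03 and Irf1 at 0.39. The medians of these 2 lists were below 0 under plain CPM, at -0.30 and -0.24.

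Lower at 11.1 mM with vehicle were mitochondrial chaperones (-0.88, percentile 0.01; 7 of 12 lower), with Lonp1 (-1.26), Hspa9 (-1.2) and the protease gene Clpp (-1.07), and apoptosis and p53 genes (-0.60, percentile 0.19), with the cyclin gene Ccng1 (-1.41), the cell death gene Bax (-0.91) and Phlda3, higher in another class (-2.59). So were the integrated stress response (-0.49, percentile 0.18; 14 of 34 lower, 2 higher) and nuclear oxidative phosphorylation genes (-0.34, percentile 0.75; 19 of 74 lower), with Ndufs7 of complex I (-1.06) and Cyc1 of complex III (-0.98). By size 576 of 5901 genes were at least 1.5-fold higher and 1185 lower in beta-like cells. Plain CPM gave 239 and 2785 (median shift -0.40), CPM without hormone and mitochondrial genes 902 and 729 (shift 0.18), and the mean of per-cell CPM 856 and 823.

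**Figure D4:**
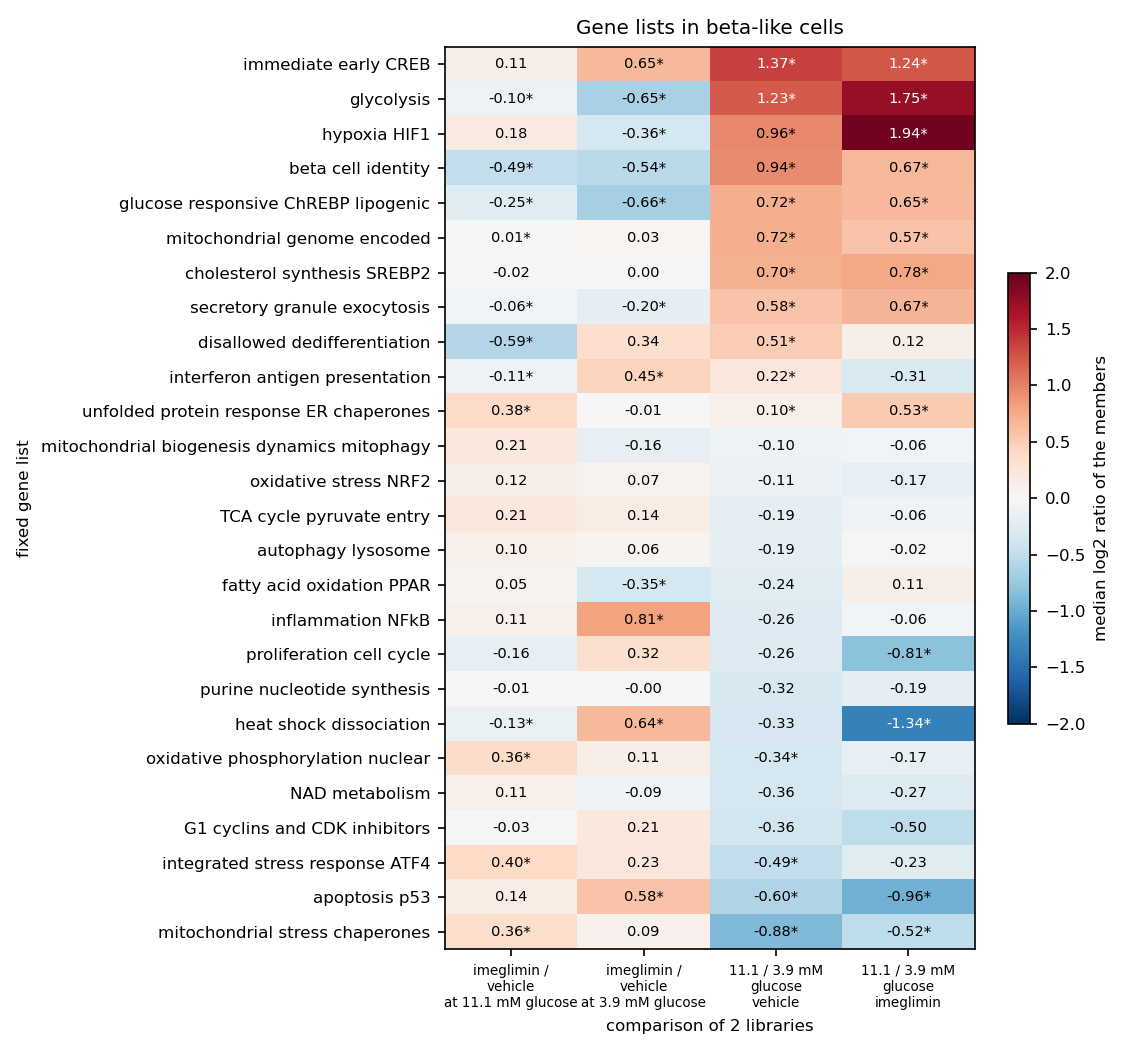
Median log2 ratio of the members of each fixed list in beta-like cells in the 4 comparisons; a star marks lists that stood apart from matched random lists.

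High against low glucose with imeglimin: beta-like cells at 11.1 mM again held more transcripts of G6pc2, Mafa, Pdyn and Ttyh1 and of glycolysis and hypoxia genes. Ins1 and Ins2 were higher too, both by less than with vehicle. Heat shock and p53 genes were lower as groups. Lower too were Ddit3 and the snoRNA hosts Snhg1 and Snhg15. Over genes the ratio correlated with that under vehicle (r 0.72), with no library shared.

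The mitochondrial adenylate kinase gene Ak4 was at 25.2 CPM at 11.1 mM and 0.209 at 3.9 mM in imeglimin beta-like cells (6.91, 6.07 to 7.92), Ttyh1 at 60.7 and 0.609 (6.64) and G6pc2 at 799 and 26.1 (4.94, 4.86 to 5.02). Pdyn was at 148 and 13.9 (3.41), Scd2 at 175 and 21.3 (3.04) and the fatty acid receptor gene Ffar1 at 30.9 and 4.34 (2.83). Next to these stood the glycogen synthase gene Gys1 (3.87), the leucine-rich repeat gene Lrrc10b (2.98), Pde10a (2.96), the huntingtin partner Hap1 (2.88) and Mrln (2.77). Lowest were Snhg1 at 54.5 and 744 CPM (-3.77), Snhg15 (-3.47), Snhg12 (-3.13), Derl3 (-3.02) and Snhg5 (-2.70), then Epb41l4aos (-2.61), Zfas1 (-2.56), Trpm5 (-2.43), the chromatin gene Hmgb2 (-2.43), Bbc3 (-2.36), Akr1c19 (-2.28) and Ddit3 at 396 and 1875 (-2.24). Counting intervals of the 84 named genes had a median width of 0.17, the widest 1.94 for Ldha.

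Under imeglimin, Mafa was at 310 and 45.8 CPM (2.76) at high against low glucose in beta-like cells, Ins1 at 1.82, Slc2a2 at 1.26, Iapp at 0.93, Ins2 at 0.40 and Adsl at 0.16. Ppp1r15a (-1.19), Trib3 (-0.67), Mki67 (-0.31), Nampt (-0.27) and Hspa5 (-0.18) were lower and Atf4 was level (0.03). Higher in other classes were Txnip (-0.47), Gcg (-0.16), Cdkn1a (-1.15) and Gdf15 (-2.66).

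Hypoxia genes were at 1.94 (percentile 100; 12 of 15 higher) in imeglimin beta-like cells at 11.1 mM, with Bnip3 (2.68) and Ldha (9.0, higher in another class). Glycolysis was at 1.75 (percentile 100; 15 of 19 higher), with Pgk1 at 524 and 83.1 CPM (2.66), Eno1 (2.26) and Pfkp (2.26). Immediate early genes were at 1.24 (percentile 100), with Crem, a cAMP-responsive factor (1.67), and Nr4a2, higher in another class (4.19). Cholesterol synthesis was at 0.78 (percentile 100), with Insig1 (1.32) and Sqle (1.04), and secretory granules at 0.67 (percentile 100), with Ptprn (2.19) and Pam (2.09). Identity genes were at 0.67 (percentile 100; 15 of 27 higher, 3 lower), with the transcription factor gene Pdx1 at 1.87. ChREBP targets were at 0.65 (percentile 99.97), mitochondrially encoded genes at 0.57 (percentile 99.89), with mt-Nd3 (1.92) and mt-Nd1 (1.29). The unfolded protein response was at 0.53 (percentile 100; 14 of 30 higher), with Sec24d (1.67) and Edem2 (1.64). Downwards stood heat shock (-1.34, percentile 0; 8 of 11 lower), with Dnajb1 (-2.09), Hspa8 (-2.02) and Hsp90aa1 (-1.98), and apoptosis and p53 (-0.96, percentile 0; 13 of 17 lower), with Bbc3 and Trp53inp1 (-1.41). Lower too were proliferation (-0.81, percentile 0.12), with Stmn1 (-0.93) and Pcna (-0.81), and mitochondrial chaperones (-0.52, percentile 2.41), with Hspe1 (-1.2) and Clpp (-0.89). In the deep cells described above, mitochondrial chaperones no longer stood apart (-0.49, percentile 2.71) and interferon genes did (-0.41, percentile 2.34). The integrated stress response list did not stand apart (-0.23, percentile 19.9).

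By size 915 of 6045 genes were at least 1.5-fold higher and 1442 lower at 11.1 than at 3.9 mM in imeglimin beta-like cells. Plain CPM gave 677 and 1874 (median shift -0.14), CPM without hormone and mitochondrial genes 1219 and 1055 (0.15), and the mean of per-cell CPM 1137 and 987. A beta-like cluster led by the hypoxia genes Ero1l and Bnip3 held 4.96% and 11.8% of vehicle cells at 3.9 and 11.1 mM, and 0% and 14.7% of imeglimin cells.

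Alpha-like cells with imeglimin: genes of the integrated stress response were higher at both glucose levels, among them the one-carbon enzyme gene Mthfd2 and, at 3.9 mM, the serine synthesis gene Psph. Mt1, Mt2 and Vgf were higher at both too. The endothelin gene Edn3, the kinase genes Pdk4, which restrains pyruvate entry, and Mapk15 were lower at both. Glucagon transcripts were nearly level. At 11.1 mM Mt1 was at 4327 CPM with imeglimin and 567 with vehicle (2.93, 2.87 to 2.99), Mt2 at 1044 and 150 (2.79), and Lbh, a transcription cofactor gene, at 2.34. Vgf was at 361 and 77.0 (2.23) and Mthfd2 at 113 and 30.0 (1.92). Lowest were Edn3 at 15.2 and 112 (-2.88), Mapk15 at -2.48, the glutamate receptor gene Gria3 at -2.0, Pdk4 at 25.7 and 96.8 (-1.91) and the fibrinogen gene Fgb at -1.79. At 3.9 mM Mthfd2 was at 270 and 35 (2.95), Psph at 84.8 and 12.6 (2.75), Mt1 at 6913 and 1300 (2.41), Vgf at 2.26 and Mt2 at 2.23. Lowest there were Edn3 at 8.93 and 99.9 (-3.48), Mrln at -3.46, Pdk4 at 11.8 and 98.0 (-3.06), Mapk15 at -2.92 and Ddc at -2.89. The median width of the counting interval over the named genes was 0.50 at 11.1 mM and 0.58 at 3.9 mM. Outside the naming rule and chosen after its values were seen, Ddit3 was at 183 and 29.4 CPM at 11.1 mM (2.64) and at 519 and 78.6 at 3.9 mM (2.72). Another class was over 10 times higher in a library.

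The integrated stress response list had a median of 1.08 in alpha-like cells at 11.1 mM (percentile 100; 26 of 34 higher, 0 lower) and 1.64 at 3.9 mM (percentile 100; 30 of 34 higher, 1 lower). Nuclear oxidative phosphorylation genes were at 0.23 (percentile 99.99) and 0.23 (percentile 98.01), and immediate early genes at 0.48 and 0.40. Hypoxia genes were at 0.72 (percentile 100) at 11.1 mM and -0.02 (percentile 38.2) at 3.9 mM. Mitochondrial chaperones were at 0.22 (percentile 95.2) and 0.42 (percentile 99.2), and heat shock genes at 0.21 (percentile 78.3) and 0.52 (percentile 97.9). Lower were the beta-cell identity list (-0.30 and -0.41), which in this class covers shared endocrine genes and free beta-cell RNA, and ChREBP targets (-0.28 and -0.31). Also lower were interferon genes (-0.39 and -0.49). Left out of this class was an unnamed cluster led by alpha markers, with delta markers next, whose top genes were Ifit3, Ifit1 and other interferon genes. It held 71 imeglimin and 11 vehicle cells at 3.9 mM, and 8 and 1 at 11.1 mM. Lower too were cholesterol synthesis at 11.1 mM (-0.32, percentile 0.03) and NF-kappaB genes at 3.9 mM (-0.77, percentile 0.05). By size 206 of 3131 genes were higher and 148 lower at 11.1 mM (131 and 206 under plain CPM, median shift -0.12), and 416 of 3290 higher and 257 lower at 3.9 mM (217 and 478, shift -0.20). A single alpha-like cluster held 95.9% and 89.5% of vehicle cells at 3.9 and 11.1 mM, and another held 96.1% and 94.7% of imeglimin cells.

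Between glucose levels, glycolysis and hypoxia genes were higher and NF-kappaB genes lower at 11.1 mM in alpha-like cells. With vehicle at 11.1 against 3.9 mM the highest were the immediate early genes Fos, at 102 and 16 CPM (2.68), and Egr1 (1.51), the cytokine gene Mif (1.48), Bnip3 (1.47) and Pgk1 (1.45). The lowest were Mt1 (-1.2), Mt2 (-1.14), the transcription factor gene Cebpd (-1.06), Sbno2, of cytokine responses (-0.99), and Fgb (-0.96). With imeglimin the highest were the hypoxia gene Ankrd37 (3.48), Bnip3 (2.17) and the glycolysis genes Pgk1 (2.16), Pfkl (2.04) and Tpi1 (1.96), and the lowest were Aldh5a1 (-1.35), Psph (-1.28), Mthfd2 (-1.26), the amino acid transporter gene Slc7a5 (-1.16) and the asparagine synthetase gene Asns (-1.11). In alpha-like cells glycolysis was at 0.84 (14 of 19 higher) with vehicle and 1.30 (13 of 18) with imeglimin, hypoxia at 0.94 and 1.35, and the integrated stress response at -0.13 (percentile 1.90) and -0.84 (percentile 0; 26 of 34 lower). NF-kappaB genes were at -1.09 (percentile 0) and -0.51 (percentile 0.12), the last 0.01 with members of at least 20 CPM only. By size 28 of 3018 genes were higher and 12 lower with vehicle, the same numbers under plain CPM, and 70 of 3144 higher and 104 lower with imeglimin (89 and 70 under plain CPM).

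Delta-like cells with imeglimin: Ddit3 was higher at both glucose levels, with Mt1 and Vgf at 11.1 mM and Trib3 and Ppp1r15a at 3.9 mM. At 11.1 mM Mt1 was at 2743 and 811 CPM (1.76), Ddit3 at 185 and 57.3 (1.69), Vgf at 1.62, the angiopoietin-like gene Angptl6 at 1.42 and the collagen hydroxylase gene P4ha2 at 1.28. The signal gene Wnt4 (-1.97), the ion transport regulator gene Fxyd3 (-1.88), Mlxipl (-1.59), the elastase gene Cela1 (-1.40) and the calcium channel gene Cacna1a (-1.32) were lowest. At 3.9 mM Lhfpl2, a membrane protein gene (2.90), Stbd1, of glycogen breakdown (2.90), Trib3 at 114 and 18.6 CPM (2.61), Ddit3 at 851 and 157 (2.44) and Ppp1r15a (2.15) were highest. Lowest at 3.9 mM were the secreted glycoprotein gene Lrg1, at 0.314 CPM from 1 UMI against 56.8 (-7.50, -12.82 to -4.99), Mapk15 (-3.26), the deiodinase gene Dio1 (-2.39), the endocrine progenitor gene Neurog3 (-2.35) and the complement inhibitor gene Serping1 (-2.13). Counting intervals were wider than in beta-like cells, with a median width of 0.85 at 11.1 mM and 1.08 at 3.9 mM. The imeglimin ratios of the 2 glucose levels correlated at 0.61 over 3755 genes.

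In delta-like cells the integrated stress response list was at 0.25 (percentile 99.98) with imeglimin at 11.1 mM and 1.06 (percentile 100; 28 of 35 higher) at 3.9 mM. Heat shock genes were at 1.2 (percentile 100; 9 of 11 higher) and NRF2 targets at 0.42 (percentile 99.6) at 3.9 mM. Hypoxia genes were at 0.38 at 11.1 mM, nuclear oxidative phosphorylation genes at 0.22 and 0.27, and glycolysis at -0.29 at 3.9 mM. By size 121 of 3415 genes were higher and 118 lower at 11.1 mM, and 481 of 3562 higher and 250 lower at 3.9 mM (342 and 330 under plain CPM, 770 and 311 with clusters of each library alone). Between glucose levels with imeglimin, such clusters gave 282 higher and 407 lower against 176 and 204. All delta-like cells lay in 1 cluster.

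At 11.1 against 3.9 mM glucose, delta-like cells with vehicle were highest in Fos (2.34), Ankrd37 (2.30), the hypoxia gene Fam162a (2.04), Mif (1.72) and Bnip3 (1.69). They were lowest in Lrg1, from 3 UMIs at 11.1 mM (-5.46, -7.76 to -3.88), Ddit3 (-1.45), the defensin gene Defb1 (-1.31), the mitochondrial tRNA ligase gene Lars2 (-0.94) and Zfas1 (-0.92). With imeglimin they were highest in Ankrd37 (3.22), Peg10, an imprinted gene (2.86), Pdyn (2.42), Pde10a (2.30) and Bnip3 (2.17), and lowest in Ddit3 (-2.20), Ppp1r15a (-1.97), Trib3 (-1.87), Snhg1 (-1.77) and Snhg12 (-1.58). Glycolysis was at 1.06 (15 of 19 higher) and 1.39 (16 of 18), hypoxia at 1.31 and 1.59 and the integrated stress response at 0.06 (percentile 72.2) and -0.73 (percentile 0). Cholesterol synthesis (0.54, percentile 100) and NRF2 targets (0.16, percentile 98.3, but -0.008 under plain CPM) were higher with vehicle. With imeglimin heat shock was at -0.80 and nuclear oxidative phosphorylation at 0.07 (percentile 97.52, but -0.04 under plain CPM). By size 84 of 3346 genes were higher and 37 lower with vehicle (43 and 94 under plain CPM, median shift -0.17), and 176 of 3505 higher and 204 lower with imeglimin (119 and 355, shift -0.11).

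Dividing cells were rare among beta-, alpha- and delta-like cells. After thinning to 3000 UMIs, 5 of 4621 beta-like cells with vehicle at 3.9 mM held at least 3 of the 15 division genes (0.108%, 0.0351 to 0.252), 21 of 4316 with imeglimin at 3.9 mM (0.487%, 0.301 to 0.743), 23 of 4804 with vehicle at 11.1 mM (0.479%, 0.304 to 0.718) and 8 of 5333 with imeglimin at 11.1 mM (0.150%, 0.0648 to 0.295). Thinned to 2000 UMIs, the shares with imeglimin at 3.9 mM and vehicle at 11.1 mM were 0.206% and 0.393%, and without Hmgb2, an alternative added after the data were examined, 0.255% and 0.458%. A beta-like cluster led by the division genes Top2a and Mki67 held 24 vehicle and 4 imeglimin cells at 11.1 mM and none at 3.9 mM. Without thinning the shares were 0.984%, 3.15%, 0.782% and 0.628%. The chromatin gene Hmgb2 held much of the set's UMIs: the set summed to 69.9, 201, 57.3 and 49.8 CPM with it and 16.8, 32.9, 33.4 and 18.6 CPM without it. Among alpha-like cells 2 of 627, 1 of 1089, 1 of 589 and 0 of 816 were dividing. The last left room for up to 0.368% when 3 cells are allowed for none found, and 0.451% by the exact interval. Among delta-like cells 0 of 234, 1 of 409, 1 of 314 and 1 of 275 were dividing. With at least 2 of the 15 genes, alpha-like cells gave 5, 11, 2 and 6 cells, and delta-like cells 0, 16, 2 and 3. The limits above therefore hold only for the rule of at least 3 genes.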

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

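Some genes and lists in beta-like cells had imeglimin ratios of opposite direction at the 2 glucose levels, by a rule set before the data were examined. All tests of the heat shock result were chosen after it was seen. The difference between glucose levels was not tested, since each ratio rests on 1 library per condition.

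Nupr1, a stress-induced transcription regulator, had a log2 ratio of 1.85 at 11.1 mM and -0.80 at 3.9 mM, and the teneurin gene Tenm4 1.56 and -0.78. Txnip was at -1.26 and 1.52 (1.525 before rounding) and the AP-1 gene Junb at -0.60 and 1.16; both were over 10 times higher in another class, so free RNA bears on them. The proliferation gene Mki67 was at -1.06 and 0.85, on 1.38 to 4.19 CPM. The heat shock list had medians of -0.13 and 0.64, and the interferon and antigen presentation list -0.11 and 0.45. Yet the beta-like cluster led by interferon genes held a larger share of cells with imeglimin than with vehicle at both levels. These shares were 2.46% and 0.679% at 11.1 mM, and 6.84% and 1.92% at 3.9 mM.

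Hspa1a, Hspa1b and Hspb1 had a median log2 ratio of -3.31 at 11.1 mM, and their lower values could come from a small group of vehicle cells. Of the 2 clusters led by Hspa1a and Hspa1b, 1 held 171 vehicle and 4 imeglimin cells at 11.1 mM, the other 155 and 207. Without both clusters the median was -0.00497, and the list moved from percentile 1.15 to 90.7. The clusters were picked by these genes, so the test was void and the explanation stays open. In alpha-like and delta-like cells the median of 5 heat shock genes was 0.20 and -0.37, against -3.16 in beta-like cells. These values argue against dispersal stress alike in all cells of the vehicle 11.1 mM library. Dispersal stress that differs between classes stays open. The higher heat shock values at 3.9 mM were not addressed by these tests.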

How the results depend on the processing

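Results in beta-like cells are given under each alternative, with counts of genes at least 1.5-fold apart in parentheses for the main scaling. Alternatives chosen after the results were seen are the highest doublet scores left out, deep cells, the clusters led by Hspa1a and Hspa1b left out, Hmgb2 left out, and those in alpha- and delta-like cells. Where a value moved, the cause was not tested unless stated.

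Scaling by plain CPM gave 223 genes higher (742) and 1333 lower (625) with imeglimin at 3.9 mM, and 239 higher (576) and 2785 lower (1185) at 11.1 against 3.9 mM with vehicle. CPM without hormone and mitochondrial genes gave 127 higher (318) and 448 lower (243) with imeglimin at 11.1 mM, 389 higher (742) at 3.9 mM, and 902 higher (576) and 729 lower (1185) between glucose levels with vehicle. The mean of per-cell CPM gave 174 higher (318) with imeglimin at 11.1 mM. The no-hormone scaling kept 39.9% of the genes higher at 11.1 mM and plain CPM 30.1% of those higher at 3.9 mM. By construction these 2 scalings each move all ratios of a comparison by 1 amount, whereas the mean of per-cell CPM moves genes by different amounts. Ratios of the mean of per-cell CPM were also centred on their median, so their balance of higher and lower genes rests partly on that centring.

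Lower expression limits let in more genes with few UMIs, which by construction raised the counts. At least 5 CPM gave 590 higher (318) and 538 lower (243) with imeglimin at 11.1 mM, 1348 lower (625) at 3.9 mM, 997 higher (576) and 1803 lower (1185) between glucose levels with vehicle, and 1647 higher (915) with imeglimin. No filter gave 3293 and 4191, 4103 and 4674, 5029 and 4541, and 5481 and 5195 higher and lower in the same order of comparisons (main counts of lower genes with imeglimin between glucose levels 1442).

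In alpha-like cells plain CPM, added after the data were examined, gave 131 higher (206) with imeglimin at 11.1 mM, and 217 higher (416) and 478 lower (257) at 3.9 mM. In delta-like cells it gave 43 higher (84) and 94 lower (37) between glucose levels with vehicle and 355 lower (204) with imeglimin. Clusters of each library on its own gave in delta-like cells 770 higher (481) with imeglimin at 3.9 mM, and 282 higher (176) and 407 lower (204) between glucose levels with imeglimin.

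The share of beta-like cells was 65.3%, 51.1%, 65.3% and 64.2% in the vehicle 3.9 mM, imeglimin 3.9 mM, vehicle 11.1 mM and imeglimin 11.1 mM libraries. With at least 3000 UMIs it was 68.6%, 58.0%, 67.4% and 67.5%. Leaving out the highest doublet scores, an added alternative, gave 67.4%, 53.1%, 67.1% and 66.5%. A mitochondrial limit of 10% gave 67.4% and 54.4% at 3.9 mM. Own-library clusters gave 62.1% with vehicle at 3.9 mM, 66.7% with vehicle at 11.1 mM and 65.8% with imeglimin at 11.1 mM. Over 8 classes and 4 libraries, shares outside the main counting interval were 18 of 32 with own-library clusters, 16 with at least 3000 UMIs and 12 at resolution 0.5.

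Dividing beta-like cells with at least 2 genes made up 0.822%, 2.97%, 0.791% and 0.450%. With imeglimin at 3.9 mM the share of 0.487% was 0.206% after thinning to 2000 UMIs and 0.255% without Hmgb2, an added alternative.

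Among lists that stood apart, 5 medians were reversed in sign under plain CPM: the mitochondrially encoded list with imeglimin at 11.1 mM in beta-like cells (-0.0365, and -0.0124 with members of at least 20 CPM and -0.00507 in deep cells), the unfolded protein response (-0.30) and interferon (-0.24) lists between glucose levels with vehicle in beta-like cells, and between glucose levels in delta-like cells the NRF2 list with vehicle (-0.00769) and the oxidative phosphorylation list with imeglimin (-0.0433). The NF-kappaB list in alpha-like cells between glucose levels with imeglimin was 0.0126 with members of at least 20 CPM. In deep cells, an added alternative, fatty acid oxidation with imeglimin at 3.9 mM (-0.34) and mitochondrial chaperones between glucose levels with imeglimin (-0.49) no longer stood apart. Proliferation with imeglimin at 3.9 mM (0.34) and interferon between glucose levels with imeglimin (-0.41) did so only there. Hspb1 with imeglimin at 11.1 mM in beta-like cells was at 0.32 without the clusters led by Hspa1a and Hspa1b, an added alternative. Of 317 ratios of named genes in beta-like cells, 258 left their counting interval under plain CPM. Without hormone and mitochondrial genes 284 did, under the mean of per-cell CPM 224, and after thinning to 3000 UMIs 155. Counting intervals therefore do not cover the choice of scaling, and the sign of small ratios can rest on it.

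All 8 beta-like counts stayed within 1.5 times the main value with a mitochondrial limit of 10% or none, with thinning to 3000 UMIs and with own-library clusters, and in the added alternatives of deep cells and of leaving out the highest doublet scores. Keeping called doublets gave the same beta-like cells. The correlation between the imeglimin ratios in beta-like cells stayed within 0.05 under all 8 alternatives. Plain CPM, 1 of the 8, could by construction move it only through which genes were compared.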

Other observations

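Smaller classes also differed with imeglimin, under a naming rule chosen after the data were examined, and every test of an explanation here was chosen after the pattern was seen. In pp-like cells Ddit3 had log2 ratios of 2.71 at 11.1 mM and 2.34 at 3.9 mM, Mt1 2.12 and 1.45, Mt2 2.08 and 1.26 and the amino acid transporter gene Slc3a2 1.37 and 1.39, with Gdf15 at 1.90 and the fibrinogen gene Fgb at -1.94 at 3.9 mM. Endothelial-like cells had Mt1 at 2.32 and 1.83. Ins2 in endothelial-like cells, a measure of free RNA, was 10.9% and 10.6% of its beta-like level with vehicle and imeglimin at 3.9 mM. At 11.1 mM it was 8.17% and 3.05%. The ratios in endothelial-like cells were not corrected for free RNA. Most endothelial-like cells of both treatments lay in 1 of 2 clusters. It held 95 vehicle and 319 imeglimin cells at 11.1 mM, and 63 and 253 at 3.9 mM. The other was made up almost only of vehicle cells, with 64 and 1 at 11.1 mM and 38 and 0 at 3.9 mM. Median UMIs of endothelial-like cells were 4429 with vehicle and 2529.5 with imeglimin at 11.1 mM. At 11.1 mM the nitric oxide synthase trafficking gene Nostrin (2.71) and the vascular gene Apold1 (1.62) were higher. Lower were the peptide gene Apln at 6.91 and 400.1 CPM (-5.86, 7 against 393 UMIs), the protease gene Prss23 (-3.72), the receptor gene Kit (-2.98) and the angiopoietin gene Angpt2 (-2.74). At 3.9 mM the interferon-response genes Ifit2 (3.71), Cxcl10 (3.45) and Rsad2 (1.97) and the snoRNA host Gas5 (2.0) were higher in endothelial-like cells, and the plasminogen activator gene Plat (-3.87), Prss23 (-2.83), the transcription factor gene Sox17 (-2.36) and the chemokine receptor gene Cxcr4 (-2.02) lower.

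In macrophage-like cells the highest ratios with imeglimin at 3.9 mM were those of Cmpk2 (4.48), Rsad2 at 1426 and 101 CPM (3.82), Ifit2 (3.48), Cxcl10 (3.08) and Ifit3 (2.48), each inducible by interferon. No list was placed among random lists in these smaller classes. The creatine synthesis gene Gatm (-2.61), the chemokine receptor gene Cx3cr1 (-2.45), the mitochondrial carrier gene Ucp2 (-2.18) and Aif1, a macrophage marker (-2.02), were lower. At 11.1 mM the kinase gene Pim1 (1.68), the cytokine gene Il1b at 947 and 303 CPM (1.64), Rel (1.45) and Ccr7 (1.44) were higher, and Mmp12 (-1.74), Cd36 (-1.48), Trem2 (-1.38) and Plin2 (-1.18), of matrix breakdown and lipid uptake and storage, lower. The class joined 2 clusters, of which the one nearer to dendritic cells held 32 of 126 cells with vehicle and 67 of 150 with imeglimin at 11.1 mM, and 12 of 105 and 33 of 85 at 3.9 mM, so these ratios also hold a difference in mix. Mt1 was at -0.18 at 11.1 mM and 0.39 at 3.9 mM in macrophage-like cells and Mt2 at 0.46 and 1.44, with Ddit3 at 1.46, Atf4 at 1.55 and Mthfd2 at 2.37 at 3.9 mM. Ins2 in macrophage-like cells, a measure of free RNA, was 5.14% and 11.2% of its beta-like level with vehicle and imeglimin at 3.9 mM. At 11.1 mM it was 4.35% and 2.84%. The ratios in macrophage-like cells, that of Ddit3 included, were not corrected for free RNA.

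The list of host genes of small nucleolar RNAs was drawn up after several of its members were seen among the lowest genes at 11.1 against 3.9 mM glucose. Its values between glucose levels restate that observation: in beta-like cells 11 of 16 members were at least 1.5-fold lower with vehicle and 10 of 16 with imeglimin. With imeglimin at 3.9 mM it was higher in alpha-like (0.66) and delta-like cells (0.96), both at percentile 100, as was the integrated stress response list. The 2 lists did not always go together. In delta-like cells the host list was at percentile 68.8 with imeglimin at 11.1 mM, where the stress list was at 99.98.

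Lower medians of the beta-cell identity list with imeglimin, with Glp1r, Mafa and Slc2a2 among its lower members, could come from shallow or damaged cells in the imeglimin libraries. Among cells with at least 10000 UMIs and at most 5% mitochondrial UMIs, the median was -0.50 at 11.1 mM and -0.55 at 3.9 mM. In all beta-like cells it was -0.49 and -0.54, so the lower medians did not depend on cells outside these limits. Those cells held the smaller part of the summed UMIs, so leaving them out could move the medians little. Damage in cells that kept many UMIs was not tested. Doublets that dilute beta-cell transcripts stay open: without the highest doublet scores the median at 11.1 mM was -0.51, but this left out few beta-like cells, by scores of a caller that did not work, and 3.9 mM was not tested.

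Free RNA from beta cells could carry higher values of metallothionein and stress-response genes over into alpha-like droplets. At 11.1 mM the observed excess of Mt1, Mt2, Nupr1, Ddit3, Trib3 and Atf4 was a median of 22.5 times what that source allowed, lowest at 1.41 times for Nupr1, and at 3.9 mM, with the whole beta-like level allowed for, the median was 4.27 times. That argues against free RNA of beta cells as the source of the set at both levels. For Nupr1 it stays open, at 1.41 times at 11.1 mM and 0.19 times at 3.9 mM. Free RNA of other cells was not tested. Chance differences between single cultures or library preparations cannot be told apart from an effect of the drug: the ratios at 3.9 and 11.1 mM, which share no library, correlated at 0.86 in alpha-like cells, but each condition had 1 library.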
